A study of Mus musculus with 15 samples.

How the data were processed

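Total RNA from brown adipose tissue of 15 mice, 5 per diet, was made into paired-end libraries and sequenced by the submitters. The authors expressed the values as TPM, transcript abundance scaled to a fixed total, with one value per RefSeq transcript and library, and each library sums to 1000000 over 24022 transcripts of 18514 gene symbols. Per the labels, the submitters named the genome build mm9 and the tool edgeR without saying what each was used for. The aligner, the counting program and their versions are not given in the sources used here. The annotation at hand was built on a later genome than mm9, so no positions are printed. Transcripts are identified by the symbols and RefSeq identifiers in the table.

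Of the transcripts, 420 were at 0 in every library. Dividing out a common factor per library turned 23599 of the transcripts above 0 into whole reads within 1e-05 of a read, and 3 transcripts, Fasn among them, could not be turned back. Counted over 1 transcript per gene, the recovered depth was 4588406 to 7276953 reads per library. These reads carry no molecular identifiers, so the precision they give covers counting error only. Within a diet no library was a copy of another, since the chi-square per gene between replicates ran from 3.91 to 80.5. Libraries of different diets were not compared in this way.

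For each gene, the transcript with the highest mean was kept. Values were analysed as log2(TPM + 1) for the 12188 genes with a mean of at least 1 TPM over the 15 libraries. A linear model with 1 mean per diet was fitted to all 15 libraries with lmFit of limma 3.58.1 under R 4.3.3, followed by eBayes with a trend on the mean. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, in rosiglitazone against control, fenofibrate against control, and rosiglitazone against fenofibrate. Every fold change is on the log2(TPM + 1) scale, so for genes of a few TPM it is smaller than the ratio of the means. Errors of fold changes are standard errors and errors of TPM are standard deviations. Data were simulated with independent normal noise for each gene, and some genes were altered by known amounts. This noise leaves out the correlation between genes that the real libraries hold. A log2 change of 2 was recovered in 93.9%, 81.8% and 93.9% of genes for the comparisons above in turn. For a log2 change of 1 the shares were 47.8%, 53.7% and 43.3%.

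The design, the tests, 33 gene lists and the rule for named genes were set before the data were examined. Of these lists 31 held at least 3 measured genes and were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists within each comparison. Values given for fry are those of its directional test. Its mixed test, which counts changes in either direction, passed 14, 6 and 15 lists for the 3 comparisons in turn. No gene of the mitochondrial genome list was in the table, and fewer than 3 lymphocyte markers passed the minimum. The rule names the 10 largest rises and the 10 largest falls among called genes whose libraries do not overlap between the groups, leaving out predicted gene models and small RNAs. It also names 26 key genes whatever their result, up to 4 called members of each list or its 2 most abundant members where none was called, and the 10 largest changes shared by both agonists. Some genes that this rule or the checks of single libraries pick are not reported here. Single values per library, such as the mean of a list, were compared with exact permutation tests, two-sided and not adjusted over lists.

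The overlap of the agonists was set beside the number expected from independent lists and 20 splits of the controls. The correlation of their fold changes was set beside 100 simulations of unchanged groups with shared controls, in which libraries were shuffled over the diets. For each count of genes or lists, 100 splits of the libraries into other groups were drawn. The labels number the replicates of each diet without saying what a number shares. The deviations of same-numbered libraries from their diet means correlated in all 5 pairs of rosiglitazone and fenofibrate (r 0.17 to 0.71). However, 1 of 5 matched its own number best. Every best match lay within replicates 1 to 3 or within replicates 4 and 5. Pairing by number is thus not told apart from these sets. The value with the replicate number as a block is given beside that comparison. Alternatives covered the pseudocount, the minimum TPM, median centring, quantile normalization, rescaling without the 20 highest genes, the libraries in the fit, the variance trend, array weights, the replicate number as a block, and leaving out each library in turn. After the values were seen, further alternatives were added for sets of libraries that differ in liver transcripts, for skeletal muscle and endothelial transcripts, for the mean over transcripts, and for limma voom on the recovered reads. A planned test with edgeR and with DESeq2 on recovered reads was not run, and voom was the only fit to these reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.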

Results

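RNA was sequenced from the brown adipose tissue, the fat that burns fuel to make heat, of male F1 mice of C57BL/6J and 129S1SvImJ parents. After chow, the mice were fed a low fat diet for 2 weeks, plain (control), with 0.005% rosiglitazone, an agonist of the nuclear receptor PPARγ, or with 0.2% fenofibrate, an agonist of PPARα. Each diet had 5 mice and 5 libraries, with 4588406 to 7276953 recovered reads per library. The series is named for target genes that both receptors share in brown adipocytes, which makes the question of each comparison which transcripts each agonist changed, and which of them changed under both.

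Some differences between libraries did not follow the diets. Alb, the albumin gene of liver, was at 2.66 to 4.71 TPM in replicates 1 to 3 of every diet and at 32.8 to 50.5 TPM in replicates 4 and 5. The 20 highest transcripts held 13.9% to 16% and 17.4% to 19.6% of all TPM in these sets. Both sets hold all 3 diets. The mean of 20 skeletal muscle markers was 2.90 ± 2.97 on the log2 scale in control (SD, n = 5), 5.31 ± 0.67 with rosiglitazone and 3.68 ± 2.95 with fenofibrate, with single control libraries from 0.50 to 7.85. The mean of 15 endothelial markers was 5.48 ± 1.01, 5.53 ± 0.71 and 5.47 ± 0.85 in turn.

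**Figure D1:**
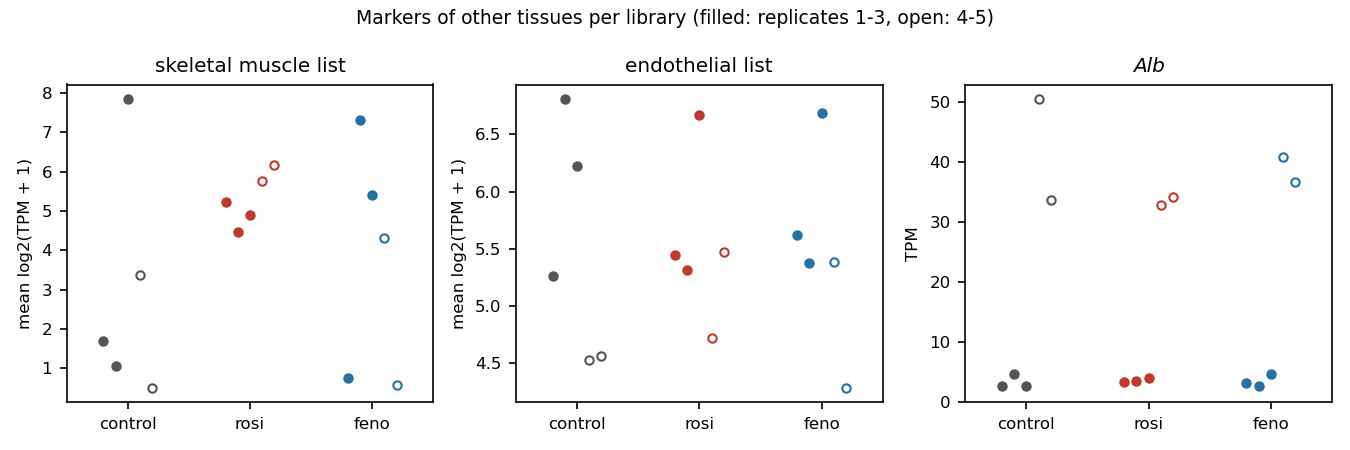
Mean log2(TPM + 1) of the skeletal muscle and endothelial markers, and TPM of Alb, in each of the 15 libraries by diet, with replicates 1 to 3 filled and replicates 4 and 5 open. Muscle markers run from 0.50 to 7.85 among the control libraries, and Alb separates the open from the filled points in all 3 diets.

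Rosiglitazone raised Acaa1b (NM_146230), a thiolase of peroxisomal fatty acid oxidation, from 54.1 ± 9.19 to 433 ± 71.1 TPM (SD, n = 5 per diet), a log2 fold change of 2.97 ± 0.19 (SE). Elovl3 (NM_007703), a fatty acid elongase of brown fat, rose 6.62-fold from 77.1 ± 24.0 to 507 ± 121 TPM. Fabp3, a fatty acid binding protein, rose 3.08-fold to 963 ± 285 TPM, and Cidec, a lipid droplet protein, rose 2.33-fold to 2411 ± 645 TPM. Ucp1 (NM_009463), the uncoupling protein that releases the proton gradient as heat, rose 1.62-fold from 5745 ± 1269.8 to 9255 ± 1556 TPM, with a log2 fold change of 0.70 ± 0.16 and an adjusted p of 0.0406. Dio2 (NM_010050), the deiodinase that makes active thyroid hormone, fell from 36 ± 6.67 to 10.8 ± 2.74 TPM, a log2 fold change of -1.67 ± 0.25.

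Of 12188 genes, 171 passed the test under rosiglitazone, 63 higher and 108 lower, and 102 of them changed over 2-fold. In 152 of the 171 the libraries of the diets did not overlap, as in 376 of all genes, where chance gives 0.794%. All 171 had the same sign within replicates 1 to 3 and within replicates 4 and 5. They were called on these same libraries, so that agreement was close to fixed. Over all genes the fold changes of the sets had r = 0.26. Within the sets 103 and 21 genes passed, and 469 passed over all libraries with these sets as a term. After Acaa1b and Elovl3 the next rises were those of the kinase Sgk2 (2.62 ± 0.27), the mitochondrial carrier Slc25a34 (2.43 ± 0.32), and the metal transporter Slc39a8 (2.38 ± 0.21). Then came Fndc5 (2.16 ± 0.34), the receptor of short chain fatty acids Ffar2 (2.10 ± 0.26), Fam131c (1.93 ± 0.29), Vil1 (1.89 ± 0.15) and Chrna2 (1.84 ± 0.26). Within diets Fndc5 followed the mean of the muscle markers most closely of the 171 called genes (r = 0.76). With that mean as a covariate it stayed called at 1.73 (adjusted p = 0.00570). Orm3, an acute phase protein gene, fell from 42.5 ± 13.0 to 3.56 ± 1.86 TPM, a log2 fold change of -3.31 ± 0.31. Other falls were those of Per2 (-2.38 ± 0.36), Cyp2b10 (-2.21 ± 0.33), Adprhl1 (-2.10 ± 0.26), and Mapk8ip1 (-2.06 ± 0.26). They were followed by Camk2b (-1.96 ± 0.28), Mgp (-1.95 ± 0.30), Timp4 (-1.88 ± 0.36), Usp2 (-1.87 ± 0.28) and Igfbp3 (-1.85 ± 0.38). The 108 lower genes include 8 Ugt1a genes with near identical changes (-0.98 to -0.93), which share exons. All 8 lost the call with the muscle mean as a covariate (adjusted p 0.0719 to 0.0852). Ugt1a1 also lost it in 10 of 15 fits without 1 library. Acaa1b and Acaa1a, Acot1 and Acot2, and Orm3 and Orm1 are close paralogs that can share reads. Acaa1a did not rise along with Acaa1b. It was at 172 ± 31.1 TPM in control and 172 ± 19.1 TPM with rosiglitazone (0.01 ± 0.14, adjusted p = 0.992).

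Lists of fatty acid handling were called up under rosiglitazone by camera at its preset correlation. In fatty acid uptake and binding, Fabp3 and Angptl4 (1.23 ± 0.28) rose among 18 measured members and none fell (6 rose and 1 fell adjusted over the list alone). The list had an adjusted p of 0.000158 and adjusted p = 0.0221 with an estimated correlation. Among 14 measured PPARα targets described in liver, Cidec rose and Acot1 (-1.78 ± 0.34), a cytosolic thioesterase, fell (4 and 1 adjusted over the list alone). The member Apoa2 was higher in replicates 4 and 5 of every diet, like Alb. This list had adjusted p = 0.000175 and adjusted p = 0.0415 with an estimated correlation, which was lost with the sets of replicates as a term (adjusted p = 0.115 with an estimated correlation). Among 28 PPARγ targets described in white fat, 21 were above 0 and Cidec alone passed (2 rose and 1 fell adjusted over the list alone). For the list adjusted p = 3.69e-06 and adjusted p = 0.0935 with an estimated correlation. Mitochondrial fatty acid oxidation had 20 of 23 members above 0, of which Acads (0.57 ± 0.12) passed (1 adjusted over the list alone). Peroxisomal fatty acid oxidation had 17 of 24 above 0, of which Acaa1b passed (3 rose and 1 fell adjusted over the list alone). Their adjusted p was 2.47e-06 and 4.99e-05, and adjusted p = 0.455 for both with an estimated correlation. In lipid droplet and lipolysis, Cidec passed among 21 members (2 rose and 2 fell adjusted over the list alone), with adjusted p = 0.0198 and adjusted p = 0.512 with an estimated correlation. By fry, uptake and binding (adjusted p = 0.00278) and the PPARα targets (adjusted p = 0.0224) passed and the other 4 of these lists did not (adjusted p 0.130 to 0.521). The mean of a list per library differed for uptake and binding (exact permutation p = 0.00794) and gave exact permutation p of 0.103 to 0.381 for the others.

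In the brown fat thermogenesis list, Elovl3 and Ucp1 rose and Dio2 fell among 23 members (3 and 2 adjusted over the list alone), with adjusted p = 0.00550 and adjusted p = 0.455 with an estimated correlation. In replicates 4 and 5 alone its direction turned down and the call ended (adjusted p = 0.551). Cidea, a lipid droplet protein of brown fat, was at 3312 ± 195 TPM in control and 4885 ± 768 TPM with rosiglitazone, a log2 difference of 0.55 ± 0.13 that did not pass (adjusted p = 0.0601). Of the 25 key genes tested, Fabp3, Angptl4 and Ucp1 rose and Dio2 fell, and 11 rose and 2 fell adjusted over the list alone. Gyk, glycerol kinase, was at 52.5 ± 34.5 and 90.6 ± 33.5 TPM (0.95 ± 0.40, adjusted p = 0.409), Ppara differed by 0.68 ± 0.22 (adjusted p = 0.194) and Pparg by -0.50 ± 0.17 (adjusted p = 0.219).

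Of the lists called down under rosiglitazone, the circadian clock list had 14 of 17 members below 0, and Gm129 (-2.73 ± 0.34), Per2, Dbp (-1.84 ± 0.32) and Tef (-1.17 ± 0.19) passed (1 rose and 9 fell adjusted over the list alone). This gave adjusted p = 4.22e-07 for the list and adjusted p = 0.0803 with an estimated correlation. In de novo lipogenesis, Elovl6 (-1.31 ± 0.20) and Acaca (-0.82 ± 0.16) fell among 19 members (4 fell adjusted over the list alone), with adjusted p = 0.000785 and adjusted p = 0.512 with an estimated correlation. In cholesterol synthesis and uptake no member of 20 passed (0 adjusted over the list alone) and 1 was above 0, with adjusted p = 0.00583 and adjusted p = 0.512 with an estimated correlation. In glucose uptake and glycolysis, Aldoc (-1.02 ± 0.19) and the gluconeogenic Fbp2 (-0.94 ± 0.18) fell among 24 members (2 fell adjusted over the list alone), with adjusted p = 0.0476 and adjusted p = 0.654 with an estimated correlation. Aldoc was near the floor, at 0.98 to 2.89 TPM in control and 0.21 to 0.63 TPM with rosiglitazone. Among 11 nerve and Schwann cell markers, Pmp22 fell (-0.78 ± 0.16; 2 fell adjusted over the list alone), with adjusted p = 0.00247 and adjusted p = 0.455 with an estimated correlation.

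Further lists were called up by camera at its preset correlation. None of the 20 skeletal muscle markers passed (0 adjusted over the list alone), while their median log2 fold change was 2.61, with adjusted p = 2.43e-08 for the list and adjusted p = 0.455 with an estimated correlation. Of 23 fibroblast and extracellular matrix genes 18 were above 0 while Dcn fell (-0.98 ± 0.17; 1 rose and 1 fell adjusted over the list alone), with adjusted p = 0.000299 and adjusted p = 0.527 with an estimated correlation. Of 7 cell division genes 6 were above 0 and none passed (0 adjusted over the list alone), with adjusted p = 0.00494 and adjusted p = 0.190 with an estimated correlation. In all 15 of 31 lists moved, 10 up and 5 down, and 16 did not (adjusted p 0.104 to 0.949). Of the 9 moved lists outside fatty acid handling, the circadian clock passed by fry (adjusted p = 0.00278) and in its mean per library (exact permutation p = 0.00794). The others had adjusted p of 0.142 to 0.671 by fry and exact permutation p of 0.0556 to 0.278. Among the lists that did not move Mest (1.08 ± 0.18), Agpat9 (0.97 ± 0.21), Foxo1 (-0.93 ± 0.20), Rgs5 (-0.96 ± 0.21) and Sparcl1 (-1.18 ± 0.27) passed as single genes.

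The rosiglitazone count was 103 without control 1, 112 without rosiglitazone 1, 103 without rosiglitazone 2, 106 without rosiglitazone 4. It was 103 with only these diets in the fit, 106 with the muscle mean as a covariate, 362 with array weights, 803 with the endothelial mean and 322 with the sets and the muscle mean. The split became 94 higher and 84 lower after median centring and 94 and 100 after quantile normalization, 107 and 97 without a minimum TPM, and 64 and 61 without control 3 and fenofibrate 2. Without 1 of the 15 libraries, the call was lost in 12 fits for Ucp1 (log2 0.62 to 0.80 over the fits, kept without control 5, rosiglitazone 3 or fenofibrate 5) and Sparcl1. It was lost in 10 for Angptl4, 8 for Agpat9 and Rgs5, 7 for Pmp22, 6 for Foxo1 and Igfbp3, 4 for Acaca and Acads, 2 for Fbp2 (control 1, rosiglitazone 4) and 1 for Timp4 (rosiglitazone 2). With the muscle mean as a covariate it was lost (adjusted p 0.0526 to 0.118) for Angptl4, then at 1.20 ± 0.31, Acads (0.59 ± 0.13), Acot1 (-1.61 ± 0.37), Agpat9 (1.03 ± 0.24), Acaca (-0.82 ± 0.19) and Fbp2 (-0.89 ± 0.20). The same held for Sparcl1 (-1.23 ± 0.30), Foxo1 (-0.86 ± 0.22), Rgs5 (-0.86 ± 0.23) and Pmp22 (-0.82 ± 0.18).

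**Figure D2:**
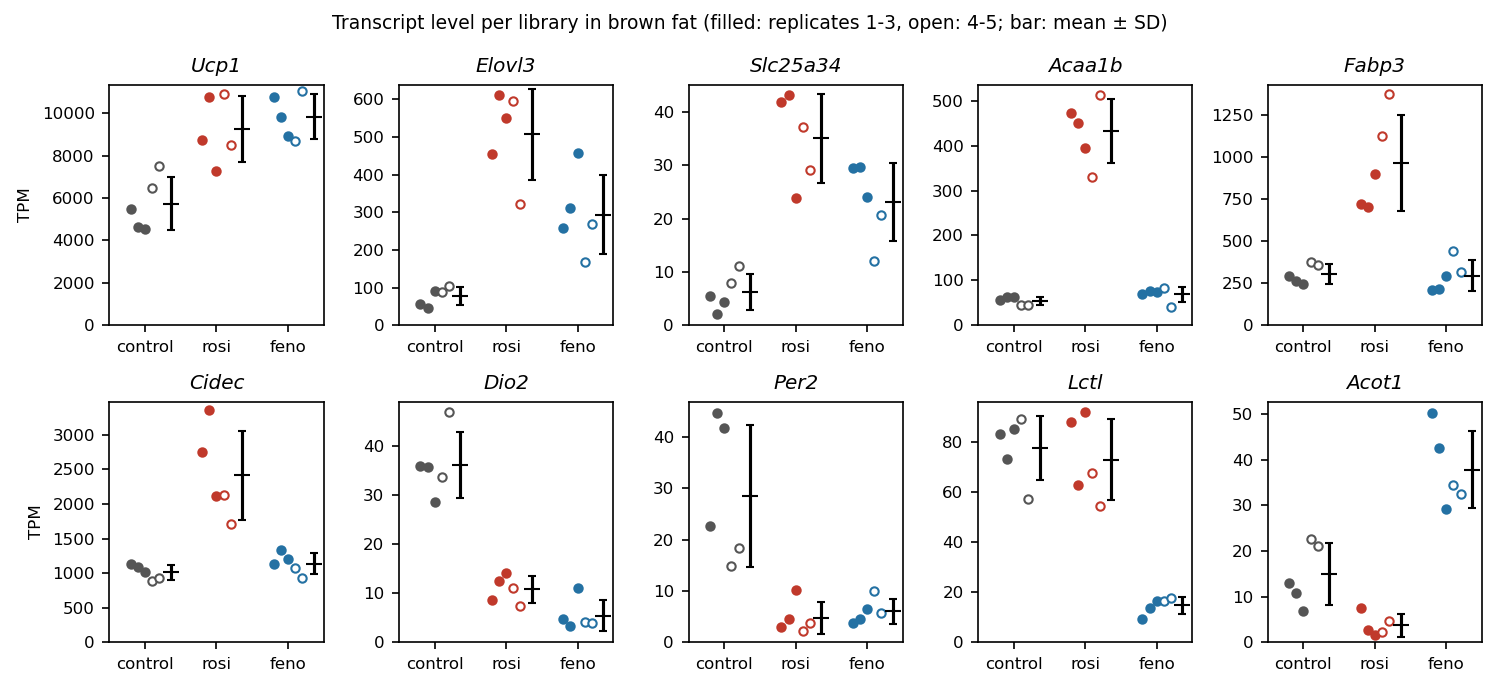
TPM of 10 genes in each of the 15 libraries by diet, on axes from 0, with replicates 1 to 3 filled, replicates 4 and 5 open, and bars for the mean and SD of 5 libraries. Acaa1b, Fabp3 and Cidec are higher with rosiglitazone than with either other diet, Lctl is lower with fenofibrate than with either other diet, and Elovl3, Slc25a34 and Ucp1 are higher and Dio2 and Per2 lower with both.

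Fenofibrate lowered Dio2 from 36 ± 6.67 to 5.46 ± 3.16 TPM (SD, n = 5 per diet), a log2 fold change of -2.61 ± 0.25 (SE). Lctl (NM_145835), a relative of lactase, fell from 77.5 ± 12.8 to 14.8 ± 3.42 TPM, a log2 fold change of -2.32 ± 0.19. Car3, an abundant carbonic anhydrase of fat and muscle, fell from 2745 ± 485 to 881 ± 222 TPM. Elovl3 rose 3.74-fold to 293 ± 105 TPM, and Ucp1 rose 1.74-fold from 5745 ± 1269.8 to 9855 ± 1057 TPM, with a log2 fold change of 0.80 ± 0.16 and an adjusted p of 0.0450. Gmpr, GMP reductase, rose from 57.1 ± 9.82 to 224 ± 117 TPM, and Cyp26b1, which breaks down retinoic acid, rose from 0.683 ± 0.438 to 10.3 ± 7.82 TPM.

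Under fenofibrate 42 of the 12188 genes passed, 11 higher and 31 lower, with 28 over 2-fold. In 40 of the 42 the libraries of the diets did not overlap, as in 338 of all genes. All 42 had the same sign in both sets of replicates, which was close to fixed, since they were called on these same libraries. Over all genes the fold changes of the sets had r = 0.22. In replicates 1 to 3 there were 10 genes that passed with limma (7 higher and 3 lower), and 0 in replicates 4 and 5. Over all libraries 1121 genes had an unadjusted p under 0.05. With limma 209 passed with the sets as a term. The largest rises after Cyp26b1 (2.46 ± 0.40) and Elovl3 (1.90 ± 0.27) were those of Slc25a34 (1.82 ± 0.32), Gmpr (1.78 ± 0.32), and Trib3 (1.29 ± 0.24). Smaller ones were those of Hebp2 (1.27 ± 0.19), the lysosomal protease Ctsz (0.94 ± 0.15), Ucp1, Bsg (0.76 ± 0.11) and Fah (0.55 ± 0.10). Further falls were those of Fkbp5 (-2.14 ± 0.37), the heat shock protein gene Hsph1 (-2.07 ± 0.40), Per2 (-1.99 ± 0.36), Zwilch (-1.95 ± 0.28), Ccrn4l (-1.86 ± 0.31), Car3 (-1.65 ± 0.22), Tsc22d3 (-1.56 ± 0.32) and Dcun1d3 (-1.41 ± 0.25). Foxo1 (-1.21 ± 0.20), a transcription factor restrained by insulin, also fell.

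Among 14 measured PPARα targets described in liver, 10 were above 0 under fenofibrate and none passed over all genes (2 rose adjusted over the list alone). One member, Apoa2, was at 1.22 to 9.64 TPM in replicates 1 to 3 and at 31.2 to 48.9 TPM in replicates 4 and 5, as other liver transcripts were. The list had a median of 0.37, adjusted p = 1.26e-05 for the list and adjusted p = 0.0175 with an estimated correlation, which was lost with the sets of replicates as a term (adjusted p = 0.149 with an estimated correlation). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, was at 58.2 ± 24.9 and 149 ± 61.7 TPM (1.34 ± 0.36, adjusted p = 0.180), and Plin2 differed by 0.38 ± 0.17 (adjusted p = 0.521). Of 23 members of brown fat thermogenesis, Elovl3 and Ucp1 rose and Dio2 fell (3 and 2 adjusted over the list alone), with adjusted p = 0.0127 and adjusted p = 0.876 with an estimated correlation. In replicates 4 and 5 alone the direction of the list turned down and the call ended (adjusted p = 0.825). Peroxisomal fatty acid oxidation (19 of 24 members above 0, 1 rose adjusted over the list alone), mitochondrial fatty acid oxidation (17 of 23 above 0, 0 adjusted over the list alone), and glucose uptake and glycolysis (17 of 24 above 0, 1 rose adjusted over the list alone) were called up by camera at its preset correlation, relative to the other genes, with no member passing. They had adjusted p = 0.00271 for the first and 0.00330 for both others, and adjusted p = 0.876 for all 3 with an estimated correlation. Of the 25 key genes tested Ucp1 rose and Dio2 fell, and 2 rose and 3 fell adjusted over the list alone. Lep, the leptin gene, was at 19.2 ± 7.90 and 5.13 ± 3.65 TPM (-1.79 ± 0.42, adjusted p = 0.117). Ppargc1a was at 13.4 ± 6.60 and 5.43 ± 1.99 TPM (-1.10 ± 0.31, adjusted p = 0.195), and Gyk at 52.5 ± 34.5 and 40.4 ± 16.5 TPM (-0.21 ± 0.40, adjusted p = 0.977).

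Fatty acid uptake and binding (11 of 18 above 0), de novo lipogenesis (13 of 19 above 0), skeletal muscle markers (20 of 20 above 0, median 0.88) and red blood cell markers (6 of 6 above 0) were also called up under fenofibrate with no member passing (0 adjusted over the list alone in each). They had adjusted p = 0.0198, 0.0219, 0.00330 and 0.0281 in turn, and adjusted p = 0.149 for the first and 0.876 for the others with an estimated correlation. Secreted adipocyte factors had 17 of 19 members below 0 and none passing (1 fell adjusted over the list alone), with adjusted p = 0.0281 and adjusted p = 0.156 with an estimated correlation. Oxidative phosphorylation was called up (adjusted p = 0.0406, adjusted p = 0.876 with an estimated correlation). However, 35 of its 78 members were above 0, none passed (0 adjusted over the list alone), and its median of -0.01 and mean of -0.01 lay above the median of all genes, -0.09. It turned down in replicates 1 to 3 alone (adjusted p = 0.864), without fenofibrate 4 (0.809), after quantile normalization (0.611) and with array weights (0.312). With the sets of replicates as a term it did not pass, nor did secreted adipocyte factors or red blood cell markers (adjusted p 0.0510 to 0.0515). With the muscle mean as a covariate the muscle markers did not pass (adjusted p = 0.0678). That covariate is the mean of these same markers, so the fit removes their mean change by construction and the loss tests nothing. With rosiglitazone the muscle markers still passed upward in that fit (adjusted p = 0.0178). By fry the PPARα targets (adjusted p = 0.0415) and secreted adipocyte factors (adjusted p = 0.00842) passed and the other 9 moved lists did not (adjusted p 0.628 to 0.986). In the mean per library secreted adipocyte factors differed (exact permutation p = 0.00794), and the others had exact permutation p of 0.0794 to 0.952. The other 20 of 31 lists did not move by camera (adjusted p 0.0526 to 0.959). Among them the mean per library of the circadian clock list differed by -0.28 (exact permutation p = 0.0397, not adjusted over the 31 lists).

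The fenofibrate count was 8 without control 1, 27 without control 2, 19 without control 3, 24 without control 4, 23 without control 5. It was 12 without fenofibrate 1, 10 without fenofibrate 2, 25 without fenofibrate 4, 8 with only these diets in the fit and 28 with the muscle mean as a covariate. It was 23 without a minimum TPM, 9 without control 3 and fenofibrate 2, 157 with array weights, 405 with the endothelial mean and 110 with the sets and the muscle mean. Median centring, which moved the median of all genes from -0.09 to 0.05, gave 13 higher and 10 lower where quantile normalization gave 12 and 11. Without 1 of the 15 libraries, the call was lost in 13 fits for Ucp1 (log2 0.72 to 0.90 over the fits, kept without control 5 or rosiglitazone 3). It was lost in 12 for Tsc22d3, 11 for Hsph1, 8 for Gmpr, 7 for Per2, Fah and Dcun1d3, 6 for Trib3, 5 for Fkbp5 and Slc25a34, 4 for Foxo1 and Ccrn4l, 3 for Ctsz and 2 for Cyp26b1 (control 1, fenofibrate 2). With the muscle mean as a covariate it was lost (adjusted p 0.0534 to 0.0781) for Trib3, then at 1.27 ± 0.24, Hsph1 (-2.08 ± 0.41) and Tsc22d3 (-1.55 ± 0.33). Of the lists 5 moved without control 2, 6 without control 3 and 6 without fenofibrate 5.

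**Figure D3:**
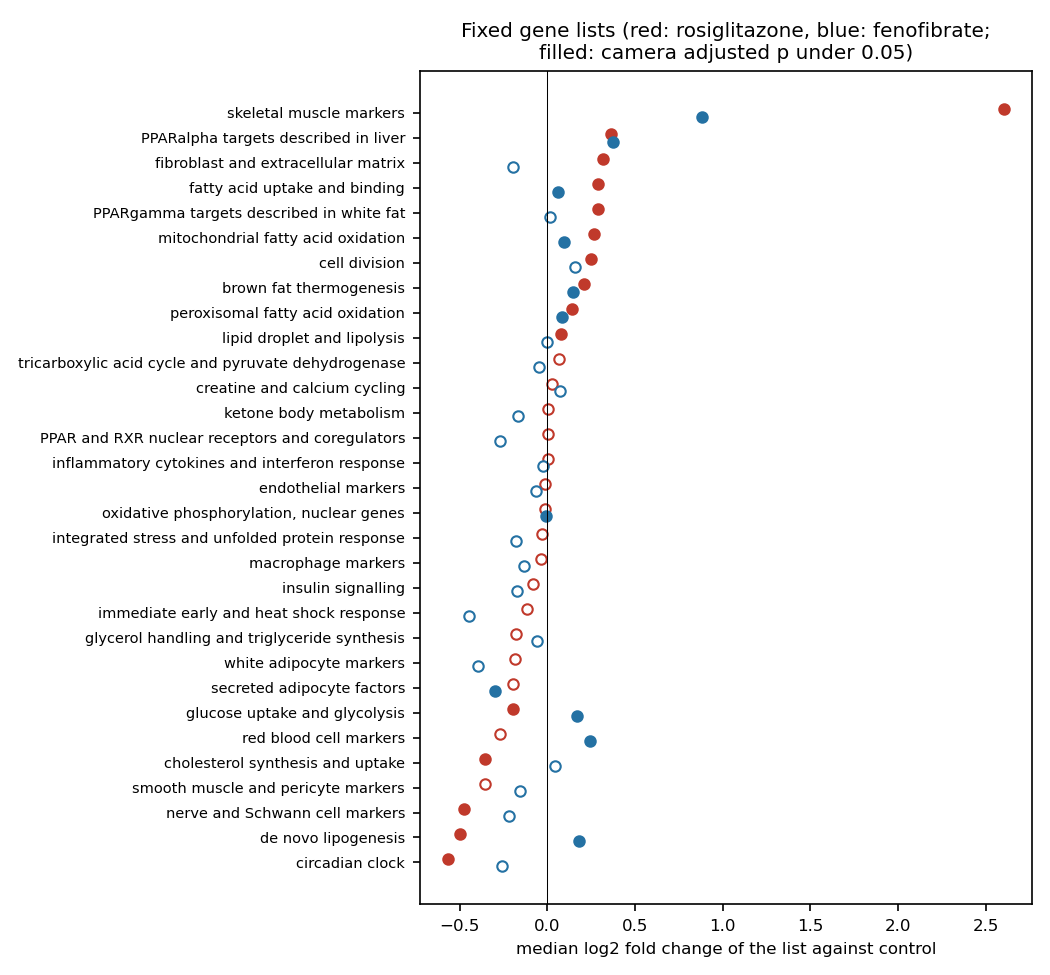
Median log2 fold change against control of each of the 31 gene lists tested, for rosiglitazone in red and fenofibrate in blue, with filled points for lists past an adjusted p of 0.05 by camera at its preset correlation. The skeletal muscle list lies farthest out, at 2.61 and 0.88, and the circadian clock list lies lowest under rosiglitazone.

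The direct comparison of the agonists gave which transcripts differ between the diets that carry them. Acaa1b was at 433 ± 71.1 TPM with rosiglitazone and 68.5 ± 16 TPM with fenofibrate (SD, n = 5 per diet), a log2 difference of 2.66 ± 0.19 (SE). Fabp3 was 3.28-fold and Cidec 2.08-fold higher with rosiglitazone, at 963 ± 285 against 294 ± 93.8 TPM and at 2411 ± 645 against 1135 ± 152 TPM. Acot1 was at 3.72 ± 2.45 TPM with rosiglitazone and 37.8 ± 8.48 TPM with fenofibrate, a log2 difference of -3.15 ± 0.34, and the lipogenic elongase Elovl6 was at 135 ± 38.8 and 384 ± 66.1 TPM. Ucp1 differed by -0.10 ± 0.16, with a 95% interval from -0.44 to 0.24 (adjusted p = 0.941).

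Between the agonists 154 of 12188 genes passed, 86 higher and 68 lower with rosiglitazone, 103 of them over 2-fold. In 145 of the 154 the libraries did not overlap, as in 371 of all genes. All 154 kept their sign in both sets of replicates, where 52 and 12 genes passed. They were called on these same libraries, so that agreement was close to fixed. Over all genes the differences in the sets had r = 0.48. With the sets as a term 516 passed, and 523 passed with the replicate number as a block, which kept all 154. Higher with rosiglitazone were Fndc5 (2.66 ± 0.34), Lctl (2.23 ± 0.19), Slc39a8 (2.10 ± 0.21), the natriuretic peptide receptor Npr3 (2.09 ± 0.29), Rbp7 (2.08 ± 0.40), Nnat (1.97 ± 0.38), Svep1 (1.94 ± 0.30), Zwilch (1.80 ± 0.28) and Arhgef37 (1.77 ± 0.33). Lower with rosiglitazone were Cyp26b1 (-3.04 ± 0.40), Orm3 (-3.01 ± 0.31), the chemokine Cxcl14 (-2.23 ± 0.28), Mapk8ip1 (-2.15 ± 0.26), Igfbp3 (-1.99 ± 0.38), Inmt (-1.98 ± 0.40), Pik3ip1 (-1.95 ± 0.34), Adprhl1 (-1.91 ± 0.26) and Mgp (-1.89 ± 0.30). Of the 25 key genes tested, Fabp3 was higher and Acot2 (-1.15 ± 0.25) lower, and 10 were higher and 1 lower adjusted over the list alone. Lctl was at 77.5 ± 12.8 TPM in control, and Zwilch at 12.5 ± 3.17 TPM. Fndc5 followed the mean of the muscle markers within diets (r = 0.76).

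The following lists were called by camera at its preset correlation, where 40 of 100 splits of the libraries, the real one included, moved at least 10 lists. De novo lipogenesis was called lower with rosiglitazone than with fenofibrate, with Elovl6 (-1.54 ± 0.20) and Acaca (-0.82 ± 0.16) passing among 19 members (3 lower adjusted over the list alone). The list had adjusted p = 1.96e-07 and adjusted p = 0.562 with an estimated correlation. Glucose uptake and glycolysis, with Fbp2 (-1.68 ± 0.18) and Aldoc (-1.0 ± 0.19, at most 2.89 TPM in any library) passing among 24 (3 lower adjusted over the list alone), was lower as well (adjusted p = 1.47e-05, and adjusted p = 0.562 with an estimated correlation). So was the circadian clock, with Gm129 (-1.71 ± 0.34) and Dbp (-1.68 ± 0.32) passing among 17 (5 lower adjusted over the list alone) with adjusted p = 3.41e-05 and adjusted p = 0.562 with an estimated correlation. Cholesterol synthesis and uptake (0 of 20 passing, 2 lower adjusted over the list alone) and red blood cell markers (0 of 6, 0 adjusted over the list alone) were lower at adjusted p = 0.000479 and 0.0208. These became adjusted p = 0.562 and 0.728 with an estimated correlation. White adipocyte markers, with Nnat, Psat1 (0.97 ± 0.22) and Mest (0.79 ± 0.18) passing among 11 (4 higher adjusted over the list alone), were higher. So were PPARγ targets described in white fat, with Gpr81 (1.21 ± 0.26) and Cidec passing among 28 (8 higher adjusted over the list alone; adjusted p = 0.00582 for both lists, adjusted p = 0.562 for both with an estimated correlation). Fibroblast and extracellular matrix, where Dcn (-1.15 ± 0.17) was lower while 19 of 23 were above 0 (3 higher and 1 lower adjusted over the list alone), skeletal muscle markers (18 of 20 above 0, 0 adjusted over the list alone) and PPAR and RXR receptors with their coregulators (11 of 15 above 0, 2 higher adjusted over the list alone) were higher. They had adjusted p = 0.00163, 0.00972 and 0.0119, and adjusted p = 0.728, 0.794 and 0.728 with an estimated correlation. With the sets as a term skeletal muscle and red blood cell markers did not pass (adjusted p = 0.0527 and 0.0686), and with the replicate block red blood cell markers did not (adjusted p = 0.0560). With the muscle mean as a covariate skeletal muscle markers did not pass (adjusted p = 0.616). This tests nothing, since the covariate is the mean of these same markers. By fry none of the 10 lists passed (adjusted p 0.1 to 0.588). In the mean per library, not adjusted over lists, the circadian clock (exact permutation p = 0.00794) and white adipocyte markers (exact permutation p = 0.0317) differed. The others had exact permutation p of 0.0556 to 0.341. The other 21 lists did not differ by camera (adjusted p 0.0750 to 0.984). Among them the mean per library of secreted adipocyte factors differed by 0.19 (exact permutation p = 0.0397, not adjusted over lists). Fabp5 (1.41 ± 0.28) and Agpat9 (1.27 ± 0.21) of these lists were higher as single genes.

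Median centring gave 80 higher and 115 lower, quantile normalization gave 87 and 109, voom gave 74 and 80, the sets as a term gave 245 and 271, and a fit without a minimum TPM gave 131 and 74. Of the lists 16 moved without rosiglitazone 3. The count was 102 without control 3 and fenofibrate 2, 524 with array weights, 702 with the endothelial mean and 449 with the sets and the muscle mean. Without 1 of the 15 libraries, the call was lost in 11 fits for Mest, 10 for Psat1, 8 for Acot2, 6 for Gpr81, 5 for Inmt, 4 for Fabp5 and Gm129 and 3 for Acaca (rosiglitazone 4, fenofibrate 1, fenofibrate 2). With the muscle mean as a covariate it was lost (adjusted p 0.0776 to 0.0875) for Acot2, then at -1.09 ± 0.27, Psat1 (0.87 ± 0.22) and Mest (0.77 ± 0.19).

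Both agonists changed 18 genes the same way, 5 higher and 13 lower, and none in opposite directions. Elovl3 rose by 2.73 ± 0.27 with rosiglitazone and 1.90 ± 0.27 with fenofibrate on the log2 scale (SE, n = 5 per diet), Slc25a34 by 2.43 ± 0.32 and 1.82 ± 0.32, and Ucp1 by 0.70 ± 0.16 and 0.80 ± 0.16. Hebp2 and Ctsz were the other shared rises. The call of Ctsz with rosiglitazone ended with the muscle mean as a covariate (adjusted p = 0.0507). Dio2 changed by -1.67 ± 0.25 and -2.61 ± 0.25, the clock gene Per2 by -2.38 ± 0.36 and -1.99 ± 0.36, and Cyp2b10 by -2.21 ± 0.33 and -1.76 ± 0.33. Tsc22d3 (-1.83 and -1.56) and Fkbp5 (-1.60 and -2.14), which glucocorticoids induce, Slc10a6 (-1.75 and -1.52), Atl2 (-1.0 and -1.22) and Tle3 (-0.98 and -1.07) were lower under both, as were Foxo1, Map2k6, Max, Mbd1 and Gm9047. None of the 18 passed the direct test between the agonists (adjusted p 0.0949 to 0.986). Within replicates 1 to 3 and replicates 4 and 5, Ucp1 differed from control by 0.86 and 0.46 with rosiglitazone and by 1.01 and 0.49 with fenofibrate.

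Independent lists of these sizes would share 0.0569 genes upward and 0.275 downward, a number that leaves the shared controls out of account. Across genes, which are not independent replicates, the fold changes of the agonists had r = 0.44. Simulations without a diet effect, with shared controls, gave a mean of 0.46 with 95% of runs between -0.16 and 0.87. They shuffled the libraries over the diets and so did not keep the sets of replicates balanced. Their values are thus not those of shared controls alone. With the controls split between the agonists, r was -0.31 to 0.26 over 20 splits and 0 to 3 genes passed in both. These fits hold fewer controls, so fewer genes can pass in them. The number shared was 59 with the sets of replicates as a term, where 2 more passed in opposite directions, 7 in replicates 1 to 3, 0 in replicates 4 and 5, and 10 after median centring. It was 7 with the muscle mean as a covariate. With rosiglitazone this ended the call of Fkbp5 (-1.67 ± 0.42), Atl2 (-0.84 ± 0.22), Ctsz, Max, Map2k6, Foxo1 and Mbd1 (adjusted p 0.0507 to 0.159). With fenofibrate it ended that of Tsc22d3 (-1.55 ± 0.33), Cyp2b10 (-1.73 ± 0.34), Slc10a6 (-1.50 ± 0.31) and Tle3 (-1.10 ± 0.21). The number shared was 45 with array weights, with 1 more in opposite directions, and 33 with the sets and the muscle mean. With the endothelial mean as a covariate it was 124, with 10 more in opposite directions. It was 8 without a minimum TPM, 10 after quantile normalization, 2 with only the groups compared, 11 with voom, and 5 without control 3 and fenofibrate 2. Without 1 library it was 2 without control 1, 6 without control 2, 7 without control 3, 10 without control 5, 9 without rosiglitazone 1 or 5, 7 without rosiglitazone 2 or 4, 3 without fenofibrate 1, 4 without fenofibrate 2, 7 without fenofibrate 3 and 11 without fenofibrate 4 or 5. The call was lost in 13 fits for Fkbp5 with rosiglitazone, 11 for Slc10a6, 8 for Cyp2b10 and 5 for Atl2 with fenofibrate, 7 for Atl2 with rosiglitazone, and 8 and 12 for Tle3 with rosiglitazone and fenofibrate.

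**Figure D4:**
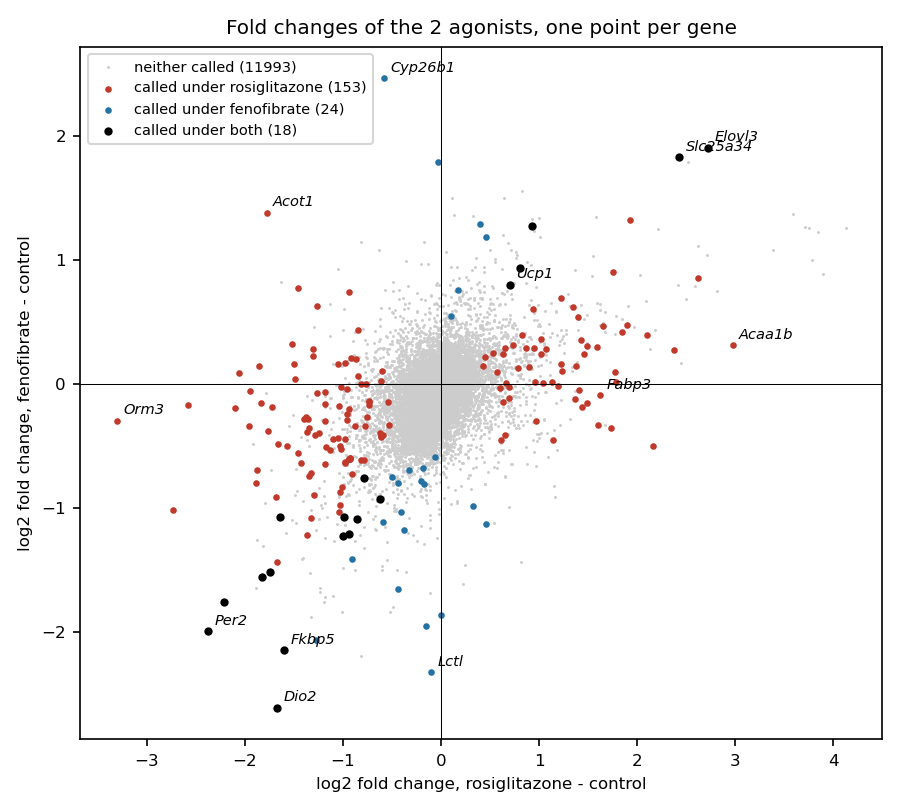
Log2 fold change of each of 12188 genes under rosiglitazone (horizontal) and fenofibrate (vertical) against the same control libraries, coloured by whether the gene passed under one agonist, the other or both. The 18 genes past the test under both, in black, lie in the upper right and lower left, and Acot1 and Cyp26b1 lie in the upper left.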

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

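The tests of muscle transcripts were chosen only after the values were seen, and the test of liver genes was written before those genes were looked at.

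Single libraries stood apart from the other 4 of their diet in 19 of 423 groups of values checked over 141 genes, 4.49% where chance gives about 1 in 20. The number in parentheses is the gap to the nearest library as a share of the group's range, for the 18 named below. In fenofibrate 3, Acat1 (0.747) and Fdft1 (0.719) were low and Ccrn4l (0.784) and Dio2 (0.731) high. In fenofibrate 4, Agpat2 (0.879) and Nnat (0.735) were low and Ech1 (0.904) was high. In fenofibrate 5, Acaa1b (0.766, at 41.1 TPM where the others lay between 69.8 and 82.1) and Fam131c (0.739) were low and Vnn1 (0.837) was high, and Camk2b (0.760) was high in fenofibrate 2. In rosiglitazone 2, Ffar2 (0.780) was low and Trib3 (0.744) high, and Cidea (0.722) was high in rosiglitazone 5. Among the controls, Fdft1 (0.833) was high in control 1, Thrsp (0.879) low in control 2, Npr3 (0.878) high in control 4 and Cxcl14 (0.712) high in control 5.

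Liver transcripts were higher in replicates 4 and 5 of all 3 diets. RNA or reads from liver in these libraries is a candidate explanation. Of 30 liver genes, of which 10 also passed the minimum of 1 TPM here, 27 were higher in replicates 4 and 5, with a median ratio of 5.34, as liver material needs. Alb reached 50.5 TPM, Apoa2 48.9 and Apoa1 19.3. The sets also differed beyond liver genes. Among endothelial markers, Kdr was at 61.9 to 178 TPM in replicates 1 to 3 and at 22.4 to 58.5 TPM in replicates 4 and 5. The ranges of Pecam1 and Cdh5 overlapped. Cox8b, of the oxidative phosphorylation list, was at 5491 to 10881 TPM and at 14728 to 26360 TPM in turn. The liver test does not speak to these genes. The labels give no group that follows these sets, so no biological explanation was tested, and how liver transcripts came into the libraries stays open.

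Skeletal muscle transcripts ranged over Acta1 from 0.850 to 2240.4 TPM and Ckm from 0 to 1330.5 TPM. Muscle carried along with the dissected fat is a candidate explanation: 27 muscle genes outside the fixed list, all past the minimum of 1 TPM here, followed its mean within diets with a median r of 0.946 over 15 libraries and a median rho of 0.907 (permutation p = 1e-05, the smallest that 100000 permutations can give), and r was 0.846 without the 2 libraries farthest out. A rise brought about by rosiglitazone cannot be told apart from it, since the difference of 2.41 in the list mean had an exact permutation p of 0.119 with 5 libraries per diet. Carried-over muscle as the source of the genes called under rosiglitazone is argued against by the fit with the muscle mean as a covariate. In it 97 of the 171 stayed called, and the median size of the log2 fold change of the 171 went from 1.13 to 1.12. All 171 kept their sign, which adds little, since they were called on these same libraries. The other 74 calls ended with a standard error that was larger in 72 of them (median 0.205 before and 0.224 after) and a median size of 0.93 before and 0.91 after, and the design leaves open how far the muscle mean and rosiglitazone can be separated.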

How the results depend on the processing

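Some alternatives were chosen after seeing the data: the sets of replicates, the muscle and endothelial covariates, and the fit without control 3 and fenofibrate 2. So were the mean over transcripts and voom. The causes below were not tested except where fewer libraries were used. The planned edgeR and DESeq2 fits were not run, and voom was the only fit to recovered reads. Counts are given in the order rosiglitazone, fenofibrate, difference, shared. Without 1 library they ran from 103 to 172, 8 to 48, 105 to 169 and 2 to 22, and lists moved from 14 to 18, 5 to 12 and 8 to 16. Only the 2 groups compared gave 103, 8, 107 and 2. Without a filter fenofibrate had 23 and shared 8. Median centred values gave 23 and 10, with 5 fenofibrate lists, and quantile normalized values 23 and 10, with 3 lists. Array weights gave 362, 157, 524 and 45, with 1 more in opposite directions and 5 fenofibrate lists. For each agonist against control, same-numbered libraries deviated together with r over 0.1 in 4 of 5 pairs (r -0.16 to 0.61 and -0.21 to 0.68). They matched their own number best in 2 of 5. Every best match lay within the same set of replicates, so these values do not tell pairing by number from the sets. The replicate number as a block gave 505, 144, 523 and 53, with 3 more in opposite directions. Replicate sets as a term gave 469, 209, 516 and 59, and with the muscle mean 322, 110, 449 and 33, with 7 fenofibrate lists. Replicates 1 to 3 only gave 103, 10, 52 and 7, and replicates 4 and 5 only 21, 0, 12 and 0, with fewer libraries. The muscle mean gave 106, 28, 124 and 7, and the endothelial mean 803, 405, 702 and 124, with 10 more in opposite directions. Without control 3 and fenofibrate 2 there were 125, 9, 102 and 5, with 6 fenofibrate lists, and voom shared 11. Of 276 results for named genes 70 changed sign in some alternative, all of them results that passed neither as reported nor there, such as Gyk with fenofibrate (-0.46 to 0.09 without 1 library). Of the lists that passed as reported or in the alternative, 3 results changed direction in planned and 4 in added alternatives, and lists that passed in neither are not counted. With fenofibrate the oxidative phosphorylation list did so quantile normalized (adjusted p = 0.611), with array weights (0.312), in replicates 1 to 3 (0.864) and without fenofibrate 4 (0.809), with 5.64e-05 to 0.809 without 1 library and up to 0.864 over all alternatives. In replicates 4 and 5 the thermogenesis list did so for rosiglitazone (0.551, the highest of alternatives from 0.000189) and fenofibrate (0.825, the highest from 0.000235), and the fibroblast list for fenofibrate (0.0484, the lowest of alternatives up to 0.999). Simulated log2 changes of 0.5 were recovered in 14.9%, 10.4% and 11.9% of genes, so small changes can be missed.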

Other observations

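The genes of the next paragraph were chosen after their values were seen, and so were the tests of glucocorticoid and clock genes and the fits with sets of replicates as a term.

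Further genes passed under rosiglitazone, with the muscle mean as a covariate, and without any 1 of the 15 libraries. Hp, haptoglobin, fell from 986 ± 165 to 440 ± 114 TPM (SD, n = 5 per diet), and Orm1 (-1.72 ± 0.28), Serpina3c (-1.35 ± 0.22) and the kininogen Kng2 (-1.50 ± 0.20) fell with it on the log2 scale (SE). The glutathione enzymes Gstm1 (-0.96 ± 0.13), Gstm2 (-1.19 ± 0.14), Gstt1 (-1.29 ± 0.21) and Gpx3 (-1.18 ± 0.22) fell, as did the parathyroid hormone receptor Pth1r (-1.67 ± 0.30). The epoxide hydrolase Ephx2 (1.48 ± 0.20), the thyrotropin receptor Tshr (1.43 ± 0.25) and Ltc4s (1.35 ± 0.21) rose. Hsd11b1, the enzyme that regenerates active glucocorticoid, was at 205 ± 50.5 TPM in control, 102 ± 21.4 with rosiglitazone and 321 ± 113 with fenofibrate, and differed between the agonists (-1.58 ± 0.25, adjusted p = 0.00362) but did not pass against control for either (adjusted p = 0.0738 and 0.455). With the sets of replicates as a term it passed against control with rosiglitazone (adjusted p = 0.0192) and not with fenofibrate (adjusted p = 0.174).

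Per2, Fkbp5 and Tsc22d3, lower with both agonists, respond to glucocorticoids, and Per2 also follows the clock. Lower glucocorticoid exposure is a candidate explanation. The test used 20 other glucocorticoid-induced genes, chosen without those seen among the calls (Mt2 was left out). Their median log2 fold changes were -0.38 with rosiglitazone and -0.33 with fenofibrate. Both lay at percentile 0 of 10000 random lists matched for level, which leave out the correlation between genes. The mean of the 20 genes per library gave exact permutation p = 0.0635 and 0.0794. Both agonists were set against the same controls, so the results are not independent. Another clock phase at dissection could account for part of the fall with rosiglitazone, where an index of 9 clock genes without Per2 differed by -1.95 ± 0.33 (exact permutation p = 0.00794), and by -1.43 ± 0.26 (exact permutation p = 0.00794) over the 6 of them that were not called. With fenofibrate the index differed by -0.40 ± 0.37 (exact permutation p = 0.325). The mean of the fixed clock list, which holds Per2, differed by -0.28 (exact permutation p = 0.0397, not adjusted over lists). With 5 libraries per diet another clock phase at dissection cannot be told apart there. The time of dissection is not given in the sources used here, and Hsd11b1 moved apart between the agonists while Fkbp5 was lower with both.

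Other splits of the same libraries into groups of 5 rarely called as many genes. For rosiglitazone 1 of 100 splits, the real one with 171, reached the count and the highest other called 1. For fenofibrate 3 of 100 reached 42, and the highest, 1589, set control 1, 2 and 3 with fenofibrate 1 and 3 against the rest, which follows the sets of replicates. Between the agonists 3 of 100 reached 154, and the highest, 1163, joined rosiglitazone 1 and 2 with fenofibrate 1, 2 and 3, the same structure. With the sets as a term and splits within them, 1 of 60 reached 209 for fenofibrate (highest other 21) and 1 of 60 reached 516 between the agonists (highest other 1). For rosiglitazone 2 of 60 reached 469, and the other, 1861, set control 2 and 3 and rosiglitazone 3, the highest of these libraries in endothelial markers (6.81, 6.22 and 6.67), with rosiglitazone 4 and 5, which points to a structure of the libraries. Few splits reached these counts of genes, which makes chance unlikely. It is not excluded where other groupings called more genes than the real one. The 18 genes shared by both agonists were reached by 1 of 100 splits (highest other 0), but splits that call few genes can share few, and they leave open what the shared controls contribute. Chance cannot be excluded for the counts of lists. For rosiglitazone 21 of 100 splits moved at least 15 lists (highest other 20, median of the others 11). For fenofibrate 36 of 100 moved at least 11 (highest other 22, median 9). Between the agonists 40 of 100 moved at least 10 (highest other 19, median 8).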
